A study of Mus musculus with 6 samples.

How the data were processed

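Total RNA depleted of ribosomal RNA was sequenced from naive CD4 T cells that had been sorted from the lymph nodes of male mice as live cells by markers that include TCR-beta and CD4 (positive) and CD44 (negative), per the labels' protocols. The 6 libraries fall into 2 groups by the genotype in their labels. Cmtr1 fl/fl mice without CD4-Cre gave 2 control libraries, and Cmtr1 fl/fl mice with CD4-Cre, a transgene that recombines floxed alleles in the T lineage, gave 4 libraries labelled Cmtr1 cKO. CMTR1 methylates the ribose of the first transcribed nucleotide next to the mRNA cap.

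The deposited values are counts of reads per gene, whole numbers and not normalized, in the layout of the STAR aligner's gene table with 1 unstranded and 2 stranded count columns. STAR 2.5.2b, edgeR, mm10 and GRCm38 are named in the submitters' processing notes, and the gene annotation used for counting is not given in the sources used here. The identifiers were matched to GENCODE vM21 on GRCm38 without their version numbers, and 46488 of 46983 genes (98.9%) matched. The matched annotation gave symbols, gene classes, coordinates, exon lengths and GC content. STAR counts a read for a gene only when it maps to 1 place and overlaps the exons of 1 gene, so reads shared by near-identical copies (multimapping) or by overlapping genes (ambiguous) are in no gene's count. The 4 rows that name no gene (unmapped, multimapping, no annotated exon and ambiguous) held 52.1% to 62.0% of all reads and were kept out of library sizes and tests. The stranded column that counts reads on the gene's own strand was used, by a rule that required at least 5 times the reads of the other stranded column in every library. The ratio ran from 5.57 in Cmtr1 cKO 3 to 22.7 in control 2.

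Gene counts came to 11949838 and 11120548 in the controls and to 10213386, 10444095, 9513874 and 11526912 in Cmtr1 cKO 1 to 4. Confidence intervals of shares are 95% Wilson intervals and the floor for a count of 0 is 3 counts per library. Both cover counting error only, since reads without molecular identifiers are not independent molecules. No replicate pair was within sampling noise. Chi-square per degree of freedom was 6.67 for the controls and 1.93 for Cmtr1 cKO 1 and 2. It was 20.1 and 19.2 for Cmtr1 cKO 4 with Cmtr1 cKO 1 and 2, and 46.2 to 54.0 for pairs with Cmtr1 cKO 3. The last values are raised by 1 gene annotated as ribosomal RNA, CT010467.1. It had 454185 counts in Cmtr1 cKO 3 and 889 to 2099 in the other Cmtr1 cKO libraries, so these values do not rank Cmtr1 cKO 3 as the most distant library. Every library was counted as 1 sample. The labels do not say that the libraries came from separate mice, so p-values measure the spread between these samples, which may be technical.

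Genes were kept by filterByExpr of edgeR 4.0.16 with its defaults (R 4.3.3), which left 12748 genes, and TMM factors scaled the libraries. Genotype was tested with edgeR's quasi-likelihood test (glmQLFit with robust settings, glmQLFTest), with genotype as the only term, and p-values were adjusted by Benjamini-Hochberg over all genes tested. A gene was called at an adjusted p under 0.05. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. CPM are read counts scaled to a common library size with the TMM factors, by edgeR's cpm function. The common dispersion was 0.00919, a biological coefficient of variation of 9.59%. On counts simulated from these libraries for 12572 genes, the same code called 34.9%, 83.6% and 98.5% of genes changed by 0.5, 1 and 2 on the log2 scale, and 15 of 12376 unchanged genes. With 82 ribosomal protein genes lowered by 1 on the log2 scale, 80 were called, that list passed the list test and 0 of 32 unchanged lists did. The simulated genes varied independently of each other, while the correlation estimated for the ribosomal protein list in these libraries was 0.92. The simulation therefore does not show how often unchanged lists of correlated genes would pass.

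A total of 37 gene lists were written before the data were examined, as were the design, the naming rule and the alternatives other than the one added later. The lists cover ribosomal proteins and other TOP mRNAs (5' terminal oligopyrimidine tract), replication-dependent histones, non-coding snoRNA hosts, snoRNAs, structured non-coding RNAs, ribosome biogenesis, cap enzymes, interferon-stimulated genes, class I antigen presentation, TCR signalling, naive identity, quiescence, effector and memory genes, regulatory T cells, immediate early genes, cytokine receptors, migration, apoptosis, the p53 response, the integrated stress response, the cell cycle, nuclear oxidative phosphorylation genes, mitochondrially encoded genes, mitochondrial ribosome, proteasome, mRNA decay, innate RNA sensing, markers of 8 other cell types or stages, and sex-linked genes. The 33 lists with at least 5 tested members were tested with camera of limma 3.58.1 on voom values with a preset correlation between genes of 0.01, and adjusted by Benjamini-Hochberg over the lists. Camera with an estimated correlation and fry, which tests whether a list moves on balance in 1 direction without comparing it with other genes, were run beside it.

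Named genes follow a rule. Cmtr1, Cmtr2, Rnmt, Rngtt and Pcif1 are always given. Among called genes with a mean of at least 1 CPM, complete separation of the genotypes and a symbol that is not a predicted gene, RIKEN clone or pseudogene, the 12 with the largest change in each direction are given. Each list adds its 2 called members with the largest change in each direction, filled up to 2 with its most abundant members. Cd4, Cd8a and Cd44 are given as markers of the sort. A few genes that this rule names, and 1 group formed after the data were seen, are not reported here. Genes and lists outside this rule were chosen after their values were seen, and are marked so.

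Alternatives changed 1 choice at a time: median-ratio size factors, upper-quartile factors, DESeq2 1.42.0, limma-voom with quality weights, no low-count filter, a filter of 1 CPM in 2 libraries, the unstranded column, protein-coding genes alone, the replicate number as a block, each library left out in turn, a log2 fold change of at least 1, and removal of the trend on gene length and GC. The share of reads in no annotated exon was added as a covariate after seeing that it differed between libraries. That share lay higher in every Cmtr1 cKO library than in every control, so the covariate overlaps with genotype and may be an effect of it. A call that ends, turns or appears under the covariate therefore does not show that the main result was technical. Ribosomal protein pseudogenes, T cell receptor alpha joining segments and the annotation classes sense-intronic and TEC (loci with transcript evidence that still await experiment) were also grouped after the data were seen.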

Results

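The series measured the RNA of naive CD4 T cells, the T cells of lymph nodes that have not yet met antigen, to ask how their transcriptome depends on CMTR1, the enzyme that 2'-O-methylates the first transcribed nucleotide of capped RNAs. There were 2 control libraries and 4 libraries labelled Cmtr1 cKO, with 9513874 (Cmtr1 cKO 3) to 11949838 (control 1) gene counts each, and n = 2 and n = 4 hold for every mean ± SD below. The share of uniquely mapped reads outside annotated exons was 37.23% (95% Wilson interval 37.21% to 37.25%) and 33.96% (33.93% to 33.98%) in the controls. In Cmtr1 cKO 1, 2, 3 and 4 it was 52.34% (52.32% to 52.36%), 51.59% (51.57% to 51.61%), 46.67% (46.65% to 46.69%) and 38.02% (37.997% to 38.04%). The group means of 35.6% ± 2.3 (SD) and 47.2% ± 6.6 (SD) gave p = 0.133 in an exact two-sided permutation test, where the smallest p that 15 splits allow is 0.0667. On the first principal component, which held 54.2% of the variance, the genotypes separated, and Cmtr1 cKO 4 lay nearest to the controls. In Cmtr1 cKO 3, 4.77% of gene counts (4.76% to 4.79%) fell on CT010467.1, a gene annotated as ribosomal RNA, against at most 0.0284% (0.0274% to 0.0294%, control 2) in the other libraries.

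The targeted gene was read first. Cmtr1 (ENSMUSG00000024019.17, chromosome 17, 29660595 to 29705979, GRCm38) had 11.19 and 11.36 CPM in the controls and 16.01, 19.77, 14.60 and 7.57 CPM in Cmtr1 cKO 1 to 4. The log2 fold change was 0.36 ± 0.31 (SE), and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment gave adjusted p = 0.461. Of the 24 exons of its main transcript, 20 are wholly shared with Gm28043, an overlapping gene on the same strand in GENCODE vM21. Counted with that annotation, reads within these exons would enter no gene's count, but the annotation used for counting is not given. Of the 6330 exon bases left to Cmtr1, 39.6% lie outside its protein-coding transcripts. Which exon was deleted is not given in the sources used here, so this count does not check the labels, and every direction below is that of the libraries as labelled. With the share of reads outside exons as a covariate the fold change turned to -0.65 (adjusted p = 0.106), and without Cmtr1 cKO 2 and 4 it was 0.17 and 0.58 (adjusted p = 0.738 and 0.0081, edgeR with Benjamini-Hochberg adjustment). Gm28043 itself, chosen after its values were seen, was higher at 9.74 ± 1.74 CPM (SD) against 4.47 ± 0.27 (SD). With that covariate its log2 fold change went from 1.12 to 0.66 and its call ended (adjusted p = 0.126).

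The other cap enzymes did not pass the test. Cmtr2, which methylates the second transcribed nucleotide, had a log2 fold change of -0.46 ± 0.14 (SE, edgeR adjusted p = 0.0533, Benjamini-Hochberg). Rnmt, the cap guanine methyltransferase, had 0.11, Rngtt, the capping enzyme, 0.07, and Pcif1, which methylates cap-adjacent adenosine, 0.09. Among 23 cap enzymes and cap-binding proteins 0 were called by edgeR (0 also when adjusted over the list alone), and Mat2a, the S-adenosylmethionine synthase, had 0.06. Without Cmtr1 cKO 4 or with quality weights 1 of the 23 was higher and 3 lower, without a filter 1 and 2, and on protein-coding genes alone or after the length and GC correction 0 and 1. With the share of reads outside exons as a covariate Cmtr2 had -0.17, Pcif1 0.17, and Rngtt and Mat2a changed sign (-0.082 and -0.013).

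Between the genotypes 1457 of 12748 genes changed, 594 higher and 863 lower in the libraries labelled Cmtr1 cKO, and 265 of them (133 higher, 132 lower) by at least 1 on the log2 scale. Phlda3, an inhibitor of AKT signalling, and Psrc1, a spindle protein, rose 11.9-fold and 11.7-fold, from 0.41 ± 0.03 to 5.05 ± 0.44 CPM (SD) and from 0.52 ± 0.36 to 6.04 ± 0.62 CPM (SD). Both are targets of p53. Dnm3 (dynamin 3) rose by a log2 fold change of 3.25 ± 0.50 (SE), Psd2 by 2.40, Adamtsl2 by 2.36, Arpp21 by 2.33, Drc1 (a dynein regulatory subunit of cilia) by 2.31 ± 0.19, Hist1h2bk by 2.04, the microRNA gene Mir7227 by 2.04, Kntc1 (a kinetochore protein) by 2.00, Hist1h3c by 1.99 and Ccdc18 by 1.89. Drc1 was the most abundant of these, at 30.2 ± 4.7 CPM (SD) against 6.02 ± 1.51 (SD). The others that rose had control means of 0.24 (Dnm3) to 0.92 (Hist1h3c) CPM. Their fold changes rest on few control reads, such as 1 and 4 for Dnm3. Prf1, which encodes the pore protein perforin of cytotoxic granules, fell to 0.259 of its control level, from 41.9 ± 8.1 to 10.9 ± 1.7 CPM (SD). Other genes that fell were Prg4 (lubricin, -2.72), Klrd1 (CD94, a lectin-like receptor, -1.91), Fcgrt (the neonatal Fc receptor, -1.70), the potassium channel gene Kcnj16 (-1.69), the small nucleolar RNAs Snora57 (-1.66) and Snord104 (-1.52), Rab4a (-1.55) and Rps12 (-1.55). Mir6236 (-2.24) and Snord100 (-1.48) are uncertain, because the first turned to 4.69 on unstranded counts, and all exon bases of the second lie inside exons of Rps12. With the share of reads outside exons as a covariate Adamtsl2 had 0.996, Mir7227 1.26, Fcgrt -0.82 and Rab4a -0.61, and without control 2 Hist1h2bk had 3.09. Snord100 had -2.22 with the covariate and Mir6236 -1.09 without control 1. None of these 7 was called there.

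In all counts by library left out below, the order is control 1, control 2, then Cmtr1 cKO 1 to 4. With a single control the test called far fewer genes, 255 without control 1 and 193 without control 2, of which 237 and 172 were among the 1457, and no called gene changed sign. Leaving out Cmtr1 cKO 1, 2, 3 or 4 gave 744, 663, 606 and 3880 genes, and the share of reads outside exons as a covariate gave 666, of which 415 were among the 1457.

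**Figure D1:**
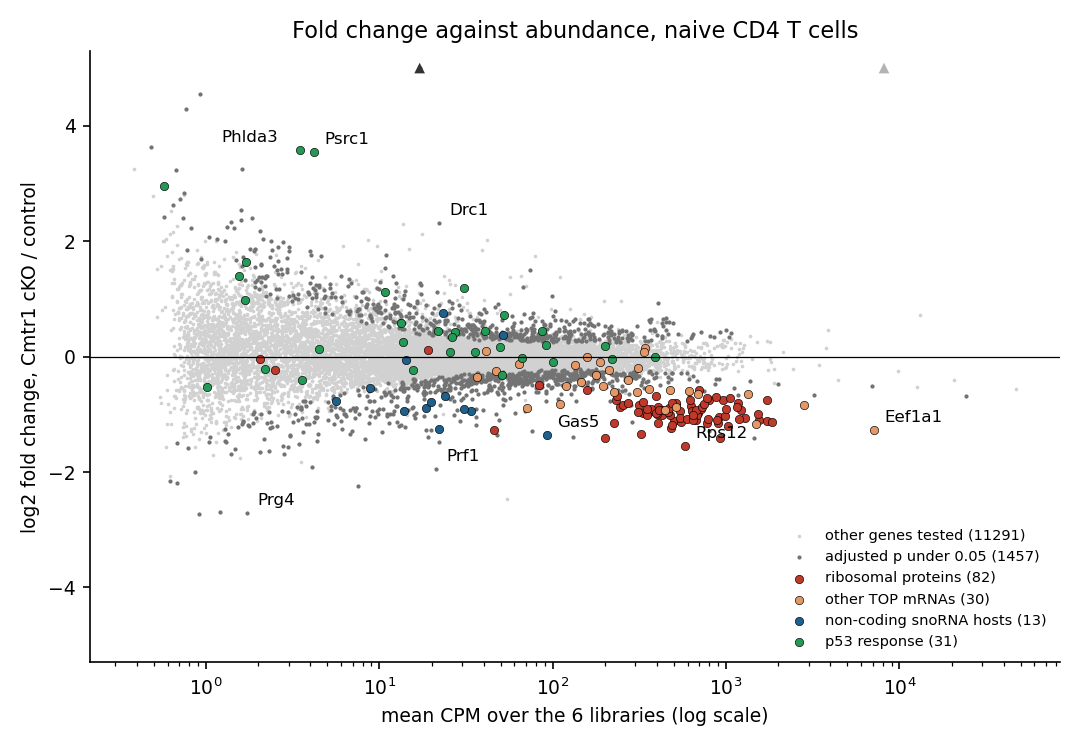
Log2 fold change between Cmtr1 cKO and control libraries against mean CPM over the 6 libraries (log scale), 1 point per gene tested, with 4 gene lists coloured; triangles at 5 are Gm33707 and CT010467.1, which lie beyond the axis. The 82 ribosomal protein genes form an abundant group with a median of -0.95, and Phlda3 and Psrc1 of the p53 list lie above 3.5.

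Messenger RNAs of the translation machinery fell together. Of 82 ribosomal protein genes 79 were lower and 0 higher by edgeR (79 adjusted over the list alone), with a median log2 fold change of -0.95, so that the list's sum went from 77200 to 39270 CPM. Rps12 went from 1031 ± 42 to 352 ± 62 CPM (SD) and Rplp1 from 1580 ± 100 to 595 ± 107 CPM (SD). The list medians against the control mean were -1.19, -1.06, -0.87 and -0.68 in Cmtr1 cKO 1 to 4. Camera gave adjusted p = 2.57e-56 for the list, and adjusted p = 0.405 with an estimated correlation. Other TOP mRNAs, which share the pyrimidine tract at their start, were lower for 18 of 30 genes and higher for 0 (21 lower adjusted over the list alone), with a median of -0.51. They include Eef1a1, the elongation factor that brings aminoacyl-tRNA to the ribosome (-1.28 ± 0.17, SE), and Tpt1 (-1.16 ± 0.14, SE). Camera gave adjusted p = 2.63e-12 for them, and adjusted p = 0.422 with an estimated correlation. With the share of reads outside exons as a covariate 75 of the 82 ribosomal protein genes stayed called lower, at a median of -0.60, and the median of the other TOP mRNAs moved to -0.21 with 10 lower and 2 higher, Tpt1 staying called at -0.75. With 1 library left out the other TOP mRNAs called lower numbered 6, 6, 18, 18, 17 and 23, and the ribosomal protein genes 72, 57, 79, 78, 78 and 79. Ribosome biogenesis factors did not move as a group, with 4 of 60 higher, among them Nop14 (0.46) and Wdr12 (0.34), and 6 lower, among them Taf1d (-0.71) and Polr1c (-0.71), by edgeR (4 and 6 adjusted over the list alone), and camera adjusted p = 0.513. With that covariate this list passed (median 0.14, camera adjusted p = 4.73e-05). Leaving out Cmtr1 cKO 1, 2, 3 or 4 gave 1, 1, 1 and 6 of these factors higher and 4, 4, 5 and 12 lower. Without control 1 Wdr12 had 0.21 and was not called.

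Non-coding host genes of small nucleolar RNAs, which guide modification of ribosomal RNA, were also lower. Gas5 went from 156 ± 5 to 60.8 ± 2.0 CPM (SD), and of 13 such hosts 9 were lower and 1 higher (10 and 2 adjusted over the list alone), with a median of -0.78. Zfas1 fell by 1.26 and Snhg15 rose by 0.76 on the log2 scale. For these hosts camera gave adjusted p = 2.06e-06, and adjusted p = 0.124 with an estimated correlation, and the host medians were -0.87, -0.81, -0.82 and -0.75 in Cmtr1 cKO 1 to 4. Hosts called lower numbered 6, 4, 8, 9, 8 and 10 with 1 library left out. Of 44 small nucleolar and Cajal body RNAs 10 were lower and 0 higher (11 and 0 adjusted over the list alone), with a median of -0.18, Snora57 and Snord104 falling most (camera adjusted p = 0.00548, and adjusted p = 0.422 with an estimated correlation). Their median moved to -0.60 after the length and GC correction, to -0.35 without control 1 or with the covariate, and to -0.30, -0.27 and -0.32 without Cmtr1 cKO 2, 3 and 4. In DESeq2, which tested 35 of them, it was -0.33. Without control 2 only 2 were called. Of 12 structured non-coding RNAs 1 was lower, Rnu11 of the minor spliceosome (-0.86 ± 0.18, SE), and 0 higher (1 and 0 adjusted over the list alone), and Rn7sk had -0.41 (-0.22 without control 2, -0.16 with the covariate). That list had a median of -0.35 and camera adjusted p = 0.0301, with adjusted p = 0.422 with an estimated correlation. The call of the structured RNAs ended without control 2 (median -0.19, adjusted p = 0.0702), without Cmtr1 cKO 2 (adjusted p = 0.0501) and with the covariate (median -0.12, adjusted p = 0.228).

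**Figure D2:**
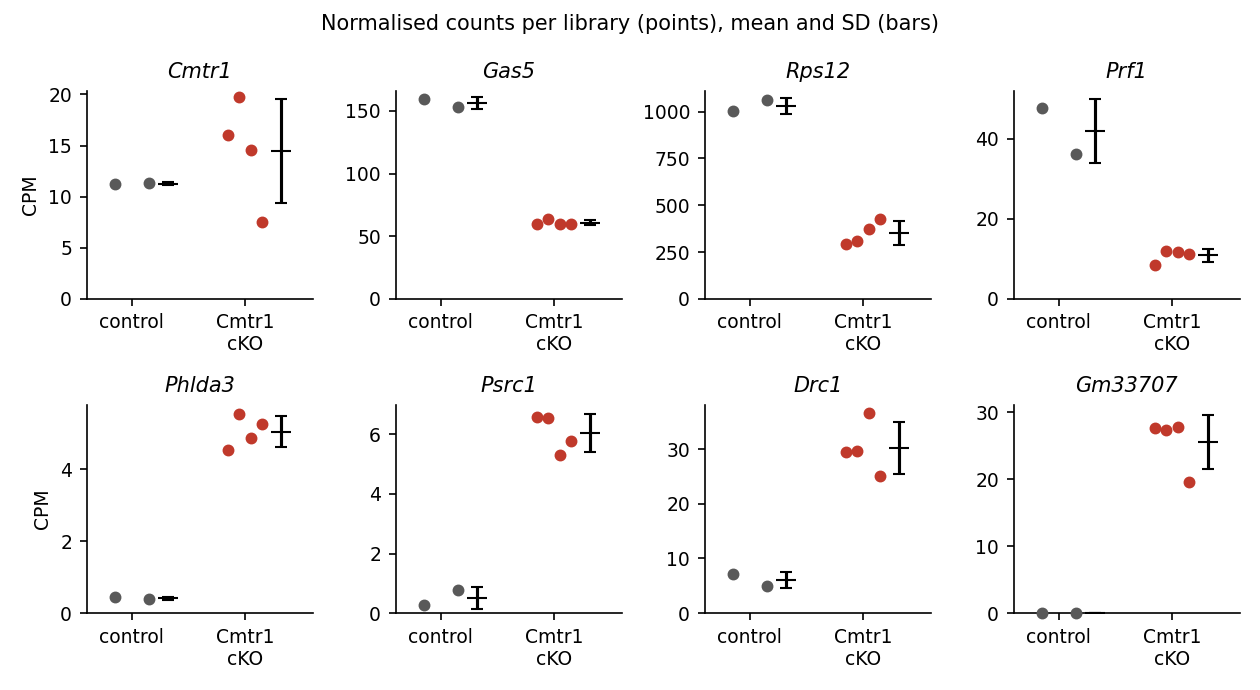
Normalised counts (CPM) of 8 genes in the 2 control and 4 Cmtr1 cKO libraries, with points for libraries and bars for mean and SD. Gas5, Rps12 and Prf1 lie lower, and Phlda3, Psrc1, Drc1 and Gm33707 higher, in all 4 Cmtr1 cKO libraries, while Cmtr1 runs from 7.57 to 19.8 CPM among them.

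Some targets of the p53 pathway and some proliferation genes rose. Of 31 p53 response genes 11 rose and 1 fell (14 and 1 adjusted over the list alone), led by Phlda3 and Psrc1, while Rrm2b, a ribonucleotide reductase subunit, fell by 0.32 on the log2 scale. The median was 0.24, with camera adjusted p = 4.36e-05, and adjusted p = 0.124 with an estimated correlation. Of 47 cell cycle genes 7 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.40. Nusap1, a mitotic spindle protein, went from 0.699 ± 0.247 to 2.503 ± 0.624 CPM (SD). Birc5 (survivin) rose by 1.67 ± 0.42 (SE), from 0.59 ± 0.15 to 1.92 ± 0.53 CPM (SD), so these 2 genes rose at low levels. Camera gave adjusted p = 2.17e-05 for the cell cycle list, and adjusted p = 0.405 with an estimated correlation. With 1 library left out 2, 3, 6, 3, 3 and 13 cell cycle genes and 4, 3, 9, 10, 7 and 16 p53 response genes were higher, and with the covariate 2 and 7. Of 53 replication-dependent histone genes, whose transcripts end without a poly(A) tail, 6 rose, led by Hist1h2bk and Hist1h3c, and 4 fell, led by Hist2h2ab (-1.36) and Hist4h4 (-0.58), by edgeR (10 and 4 adjusted over the list alone). The histone list had a median of 0.23 and camera adjusted p = 0.0212, with adjusted p = 0.648 with an estimated correlation. The histone call ended without Cmtr1 cKO 3 or 4 (adjusted p = 0.0588 and 0.154), and without control 1 its direction in camera turned (median 0.0019, adjusted p = 0.805), while the median was 0.47 without control 2 and 0.44 with the covariate. Hist2h2ab had -0.78 with the covariate and Hist4h4 -0.36 without control 2, and neither was called there. Histone genes called higher numbered 0, 2, 6, 4, 2 and 12 with 1 library left out and 10 with the covariate. Of 39 apoptosis and survival genes 7 rose, led by Birc5 and the anti-apoptotic Bcl2 (0.58 ± 0.10, SE), and 2 fell, Casp6 (-0.43) and Bcl10 (-0.32), by edgeR (8 and 2 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.465) except with the covariate (median 0.07, camera adjusted p = 0.017). With 1 library left out 1, 0, 4, 4, 3 and 8 of them were higher.

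**Figure D3:**
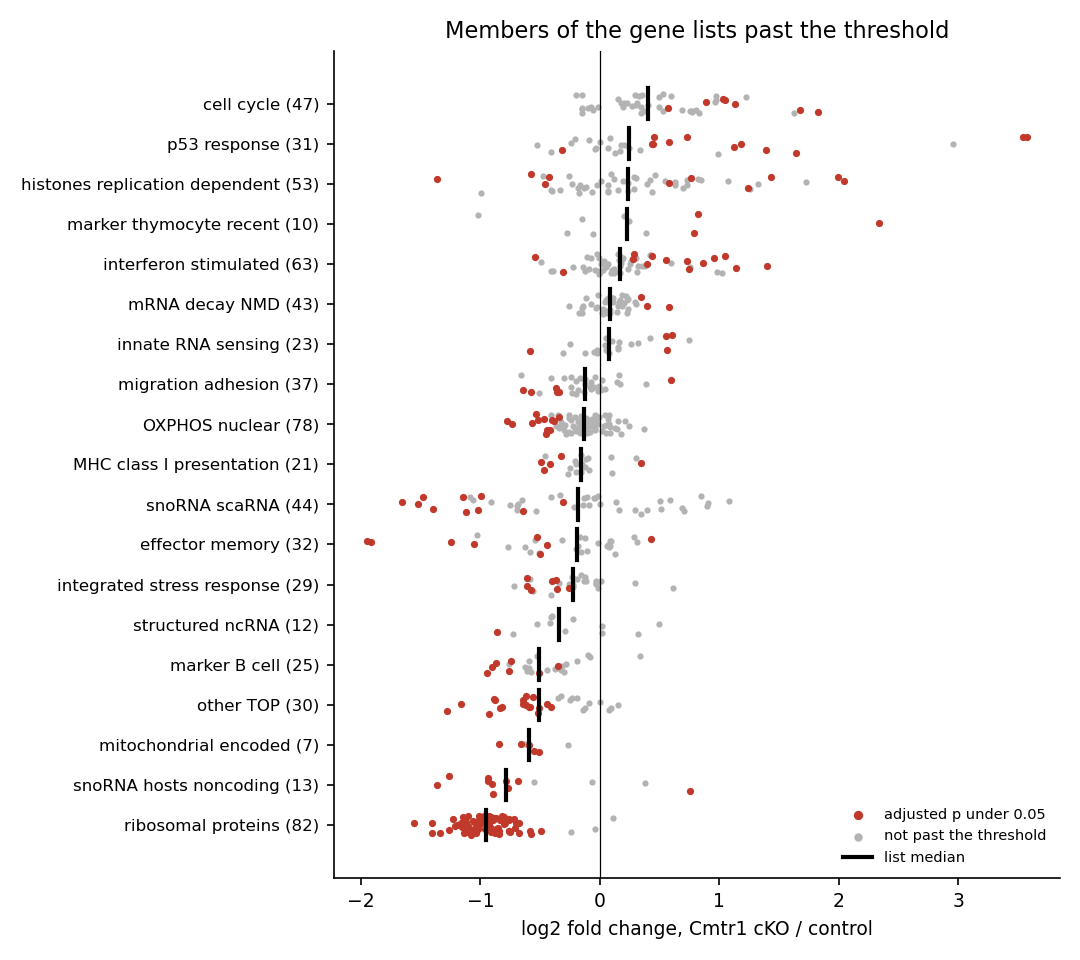
Log2 fold change of every tested member of the 19 gene lists past the threshold (number tested in brackets), with called members in red, others in grey and the list median as a black bar. Medians run from -0.95 for ribosomal proteins to 0.40 for the cell cycle.

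Antiviral genes rose in part. Of 63 interferon-stimulated genes 12 were higher and 2 lower (18 and 4 adjusted over the list alone), with a median of 0.17. Mx1 and Mx2, genes of the antiviral GTPase family, rose by 1.40 ± 0.36 and 1.14 ± 0.27 (SE) on the log2 scale, while Gbp2 fell by 0.54 and Ifit2 by 0.31. Mx2 is annotated as a polymorphic pseudogene, so its RNA need not give a working protein. Camera gave adjusted p = 2.8e-05, and adjusted p = 0.545 with an estimated correlation, and without control 2 the list did not pass (median 0.05, adjusted p = 0.467), while without control 1 the median was 0.40. With 1 library left out 16, 1, 4, 4, 8 and 16 of the list were higher, and 7 with the covariate. Mx1 had 2.44 without control 1 and 0.84 (adjusted p = 0.17) without control 2, and was at 5.69 ± 4.07 CPM (SD) in the controls. Gbp2 had -0.35 without control 1 and -0.25 with the covariate, Ifit2 had -0.17 with the covariate, and these calls ended. Of 23 innate RNA sensing genes 3 were higher, led by the kinase gene Ikbke (0.60) and Tlr7 (0.56), and 1 lower, the DNA sensor Cgas (-0.59), by edgeR (3 and 1 adjusted over the list alone). That list had a median of 0.08 and camera adjusted p = 0.039, with adjusted p = 0.531 with an estimated correlation, and its call ended without control 2 (median 0.04, adjusted p = 0.467; without control 1 the median was 0.21), Cmtr1 cKO 2 (adjusted p = 0.0501) or Cmtr1 cKO 4 (adjusted p = 0.125). With the covariate Ikbke stayed called at 0.27. Class I antigen presentation was lower for 4 of 21 genes and higher for 1 (8 and 1 adjusted over the list alone), with a median of -0.16. Tapbp (tapasin) fell by 0.49 ± 0.07 and H2-K1 by 0.47 ± 0.11 (SE), while H2-Q4 rose by 0.35. The class I list had camera adjusted p = 0.00179, and adjusted p = 0.46 with an estimated correlation, the call ended without control 1 (adjusted p = 0.0608), and with the covariate the median was -0.08. Class I genes called lower numbered 1, 1, 1, 1, 2 and 13 with 1 library left out. Class I genes are close paralogs, so their uniquely mapped counts are uncertain.

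Genes of the integrated stress response were lower for 7 of 29 genes and higher for 0 (9 and 0 adjusted over the list alone), with a median of -0.23. Mthfd2, of mitochondrial folate metabolism, and Ddit4, an inhibitor of mTORC1, each fell by 0.61 on the log2 scale. The stress list had camera adjusted p = 2.87e-05, and adjusted p = 0.405 with an estimated correlation. With the share of reads outside exons as a covariate its median was -0.14 with 4 lower, and Mthfd2 was not called (-0.37). With 1 library left out 1, 1, 5, 5, 4 and 13 were lower. Of 43 mRNA decay genes 3 were higher and 0 lower (2 and 0 adjusted over the list alone), with a median of 0.08, led by the deadenylase gene Pan2 (0.58) and the nonsense-mediated decay gene Smg6 (0.40). Camera gave adjusted p = 0.00548, and adjusted p = 0.239 with an estimated correlation. With the covariate the calls of Pan2 and Smg6 ended (0.22 and 0.066, adjusted p = 0.195 and 0.732). Decay genes called higher numbered 0, 0, 2, 2, 2 and 11 with 1 library left out.

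Among genes of T cell identity, Cd4 had a log2 fold change of 0.10 ± 0.08 (SE) and did not pass the test. Cd8a had -1.02 ± 0.39 (SE) and was not called (edgeR adjusted p = 0.104, Benjamini-Hochberg), and Cd44 fell by 0.50 ± 0.11 (SE) on the log2 scale. Of 30 naive T cell genes 2 rose, Bcl2 and the kinase gene Txk (0.37), and 6 fell, led by Dapl1 (-0.64) and Itga6 (-0.58), by edgeR (3 and 8 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.235). Of 28 quiescence genes 2 rose, Runx1 (0.42) and Tsc1 (0.33), and 5 fell, led by Btg1 (-0.48) and Klf6 (-0.43), by edgeR (2 and 5 adjusted over the list alone, camera adjusted p = 0.235). With the covariate 0 quiescence genes were higher and 2 lower, and Runx1 (0.038), Tsc1 (0.21) and Btg1 (-0.32) were not called. Of 36 TCR signalling genes 3 rose, led by Txk and Cd6 (0.32), and 1 fell, Cd247 (-0.29), by edgeR (5 and 1 adjusted over the list alone, camera adjusted p = 0.0856). That list passed without control 2 (adjusted p = 0.0222) and with the covariate (adjusted p = 0.00123). Of 37 immediate early genes 3 rose, led by Fos (0.89) and Nr4a1 (0.60), and 0 fell by edgeR (3 and 0 adjusted over the list alone, camera adjusted p = 0.41). With the covariate that list passed (camera adjusted p = 0.011), but Fos had 0.32 and was not called (adjusted p = 0.518). Of 33 cytokine receptor and JAK-STAT genes 2 rose, Cish (0.54) and Il21r (0.31), and 4 fell, led by Il18r1 (-0.53) and Ifngr1 (-0.49), by edgeR (2 and 5 adjusted over the list alone, camera adjusted p = 0.534). Il18r1 had -0.285 (adjusted p = 0.314) without control 1 and -0.79 (adjusted p = 0.0839) with the covariate, and Il21r 0.16 (adjusted p = 0.353) with the covariate. Of 14 regulatory T cell genes 0 were called by edgeR (0 adjusted over the list alone), and Izumo1r and Ikzf2 had -0.27 and 0.12. Ikzf2 had -0.13 without control 1, 0.44 without control 2 and 0.063 without Cmtr1 cKO 3. Without control 2, 0 naive, quiescence and TCR signalling genes were called, and without Cmtr1 cKO 4 these lists had 6, 5 and 10 higher and 11, 8 and 6 lower.

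Effector and memory genes were lower for 7 of 32 genes and higher for 1 (8 and 2 adjusted over the list alone), with a median of -0.19. Prf1 and Klrd1 led the fall, and Ctsw, a cathepsin of cytotoxic cells, rose by 0.43 ± 0.08 (SE). The effector list had camera adjusted p = 0.0163, and adjusted p = 0.422 with an estimated correlation, and with the covariate the list did not pass (median -0.13, adjusted p = 0.298). Effector genes called lower numbered 3, 2, 5, 4, 5 and 8 with 1 library left out. The CD8 T cell and NK markers had medians of -0.52 and -0.53, with 5 of 6 and 4 of 5 negative. Both passed fry (adjusted p = 0.0365 for each) but not camera (adjusted p = 0.14 and 0.178). The NK median was -0.20 without control 1, -0.31 without control 2, -0.33 without Cmtr1 cKO 3 and -0.35 with the covariate. Of 37 migration and adhesion genes 5 fell, led by Gpr183 (-0.65 ± 0.09, SE), a receptor for oxysterols, and Itga6, and 1 rose, Arhgap15 (0.60), by edgeR (5 and 1 adjusted over the list alone), with a median of -0.12. The migration list had camera adjusted p = 0.00707, and adjusted p = 0.422 with an estimated correlation, and the call ended without control 2 (median -0.05, adjusted p = 0.0963) and with the covariate (median -0.05, adjusted p = 0.383), where Gpr183 and Arhgap15 stayed called at -0.42 and 0.24. Migration genes called lower numbered 2, 0, 3, 2, 2 and 11 with 1 library left out. Of 10 markers of thymocytes and recent thymic emigrants 3 rose, led by Arpp21 and Sox4 (0.82 ± 0.12, SE), and 0 fell by edgeR (3 and 0 adjusted over the list alone), with a median of 0.22 and camera adjusted p = 0.0488, with adjusted p = 0.422 with an estimated correlation. This call ended with median-ratio and upper-quartile scaling (adjusted p = 0.0504 and 0.0522) and without control 1, Cmtr1 cKO 2 or Cmtr1 cKO 4 (adjusted p = 0.109, 0.0616 and 0.125), and the median was 0.38 without control 2 and 0.41 with the covariate.

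All 7 mitochondrially encoded mRNAs tested had a negative log2 fold change, 5 were called lower by edgeR (5 adjusted over the list alone) and the median was -0.59, with mt-Nd2 at -0.85 ± 0.14 (SE) and mt-Nd1 at -0.66 ± 0.12 (SE), both subunits of complex I. Camera gave adjusted p = 2.8e-05, and adjusted p = 0.422 with an estimated correlation. With the covariate their median was -0.33 with 2 called, mt-Nd1 at -0.39 among them, while mt-Nd2 (-0.51) was not called. Without control 1 or without control 2, 0 were called. Mitochondrial ribosomal RNA went from 3.44% ± 0.03 to 2.35% ± 0.25 (SD) of gene counts (exact two-sided permutation p = 0.0667, the smallest possible), and multimapping reads from 10.03% ± 0.74 to 7.52% ± 1.21 (SD) of all reads (exact p = 0.133). The RNA had been depleted of ribosomal RNA, so the share of mitochondrial ribosomal RNA may also differ with the depletion of each library, which was not tested. Of 78 nuclear oxidative phosphorylation genes 12 fell, led by Cox7a2l (-0.78) and Cox8a (-0.73), and 0 rose by edgeR (14 and 0 adjusted over the list alone), with a median of -0.13 and camera adjusted p = 8.45e-05, with adjusted p = 0.611 with an estimated correlation. With the share of reads outside exons as a covariate this list turned upward (median 0.09, 8 higher and 2 lower, camera adjusted p = 0.0177). Cox7a2l and Cox8a stayed called there at -0.40 and -0.46. The number lower was 1 without control 1 or without control 2, 6, 6 and 4 without Cmtr1 cKO 1, 2 and 3, and 32 without Cmtr1 cKO 4 (median -0.20). Of 77 mitochondrial ribosome genes 2 rose, Mrpl37 (0.51) and Mrpl42 (0.48), and 1 fell, Mrpl52 (-0.49), by edgeR (2 and 0 adjusted over the list alone). Of 37 proteasome genes 2 rose, Psmc5 (0.41) and Psmd14 (0.30), and 2 fell, Psmb4 (-0.44) and Psmb1 (-0.41), by edgeR (2 and 2 adjusted over the list alone). Neither list passed (camera adjusted p = 0.882 and 0.839), and with the covariate both passed as higher (medians 0.15 and 0.19, camera adjusted p = 1.04e-05 and 5.04e-09). Mrpl52 (-0.25), Psmb4 (-0.13) and Psmb1 (-0.11) were not called there, and Psmc5 and Psmd14 stayed called at 0.61 and 0.48.

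Markers of other cells that a sort could hold were also read. Of 25 B cell markers 7 fell and 0 rose (7 and 0 adjusted over the list alone), with a median of -0.51. The class II genes H2-Ab1 and H2-Eb1 went from 17.8 ± 0.5 to 9.22 ± 2.26 CPM (SD) and from 15.2 ± 0.5 to 8.07 ± 2.06 CPM (SD). Camera gave adjusted p = 2.8e-05, and adjusted p = 0.457 with an estimated correlation, and the list did not pass fry (adjusted p = 0.123). Without control 1 or without control 2, 0 of the 25 were called (medians -0.71 and -0.26). The median was -0.34 without Cmtr1 cKO 1 and -0.84 with the covariate. Cmtr1 cKO 2 lay at -0.10 against -0.51, -0.77 and -0.73 in Cmtr1 cKO 1, 3 and 4. Of 6 CD8 T cell markers 1 fell, Nkg7 (-1.25), and 1 rose, Ctsw, by edgeR (4 and 1 adjusted over the list alone, camera adjusted p = 0.14). Of 5 NK and innate lymphoid markers 1 fell, Klrd1, and 1 rose, Gata3 (0.33), which T cells also express, by edgeR (2 and 1 adjusted over the list alone, camera adjusted p = 0.178). Of 9 myeloid markers 1 fell, Ctss (-0.51), and 0 rose by edgeR (2 and 0 adjusted over the list alone, camera adjusted p = 0.235), and Bst2 had -0.23. Without control 2 the NK and myeloid lists passed as lower (adjusted p = 0.0264 and 9.82e-07), but without control 1 the myeloid median was 0.0062 with 0 called. With the covariate Ctss stayed called at -0.30, and Bst2 had -0.034 without control 1, -0.37 without control 2 and -0.042 with the covariate. Too few genes were tested of gamma-delta T cells (3, with Trdc at 0.33 and Blk at -0.44), stroma and endothelium (2, Pecam1 at 0.06 and Eng at 0.20), and erythroid cells and platelets (2, Hbb-bs at -1.002 and Itga2b at 0.32), and 0 of them were called by edgeR. Blk, Eng and Hbb-bs changed sign without control 2 (0.43, -0.055 and 0.22), and Itga2b with the covariate (-0.17). Of 4 sex-linked genes 1 rose, Uty (0.37), Ddx3y had 0.21, and 0 fell by edgeR (2 and 0 adjusted over the list alone). With the covariate Uty had 0.050 and was not called, and Ddx3y had -0.096.

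**Figure D4:**
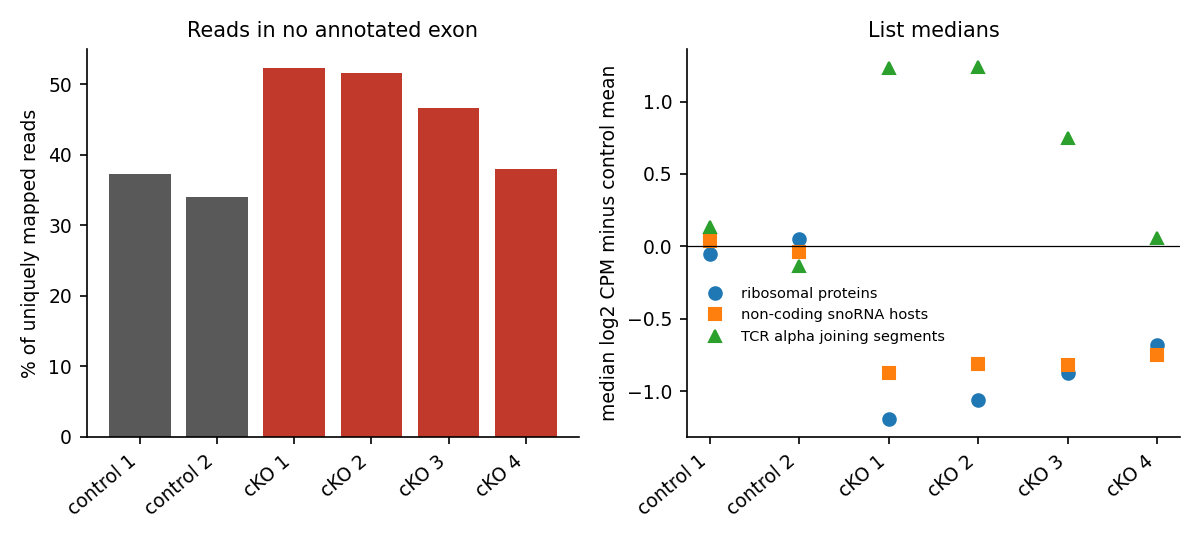
Left, percent of uniquely mapped reads in no annotated exon for each library; right, median log2 CPM of 3 gene lists in each library minus the control mean. The ribosomal protein and snoRNA host medians lie at -0.68 or lower in every Cmtr1 cKO library, while the T cell receptor alpha joining segments lie at 1.23 in Cmtr1 cKO 1 and 0.06 in Cmtr1 cKO 4.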

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

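All tests of explanations here were chosen after the pattern was seen. The outcomes of the matched-gene comparison and of the retained-intron comparison were not known when their expected results were written down, and the others had been seen.

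Of 166 values per library checked within the 4 Cmtr1 cKO libraries, 5 held 1 library far from the other 3, and chance gives about 1 in 20. Gas5 had 63.9 CPM in Cmtr1 cKO 2 against 59.4 to 60.1 in the others. Gm33707 had 19.5 CPM in Cmtr1 cKO 4 against 27.4 to 27.8. In Cmtr1 cKO 3, CT010467.1 had 48050 CPM (4.77% of gene counts) against at most 181, and 3.78% of all reads were ambiguous against at most 0.779%. In the unused stranded column, which counts reads opposite to each gene, Gm42418 held 995457 reads in Cmtr1 cKO 3 against at most 5827 elsewhere. That was 58.3% of the gene counts of that column (95% Wilson interval 58.2% to 58.4%). Gm42418 lies within CT010467.1 on the other strand, so these reads lie on the strand of CT010467.1. They belong to the same excess, and they enter the strand ratio of 5.57 of that library. Reads outside annotated exons, which no comparison counts, were above the highest control (37.2%) in every Cmtr1 cKO library, at 52.3%, 51.6%, 46.7% and 38.02%.

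The fall of the ribosomal protein mRNAs was set against 3 technical explanations. After the trend on gene length and GC was removed the median stayed at -0.89 with 79 of 82 called lower. A trend on these traits as annotated therefore does not account for the fall. Length here counts every base in any annotated exon (2027 for Rps12), which can exceed the mature mRNA. A bias on mature mRNA length was not tested. The 150 protein-coding genes nearest to them in abundance, length, GC and intron length, outside the TOP lists, had a median of -0.12 (interquartile range -0.32 to -0.03), with 33 called lower and 6 higher. This argues against a change shared by short abundant transcripts as the whole cause, but not against a smaller shared fall, and the matched genes were less abundant (median 257 against 546 CPM). They were also longer, with a median exon length of 2432.5 against 1754.5 bases and a median intron length of 1874 against 1105 bases. The match was therefore incomplete in the traits it was meant to hold equal, and its exon length is also that of all annotated exons. Ribosomal protein pseudogenes had a median of -0.995 with 17 of 38 lower and 0 higher, where uniquely mapped reads lost to them would have raised them. Reads that fit gene and pseudogene alike are multimapping and enter neither count, so the pseudogenes cannot show their loss. The multimapping share, over reads of all kinds, was lower in Cmtr1 cKO at 7.52% ± 1.21 against 10.03% ± 0.74 (SD) of all reads. A link to the genotype is a hypothesis that stays open beside a library preparation that differed with genotype, since the labels give no batch.

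The reads outside exons could come from genomic DNA or from unspliced RNA. DNA would fill both strands alike, but in 107 sense-intronic genes the gain on the opposite strand was 0.011% of the gain on their own. In 920 protein-coding genes whose annotated exon bases lie mostly in retained-intron transcripts the median log2 fold change was 0.14 above that of as many abundance-matched genes with none (bootstrap interval 0.11 to 0.18). All these genes were read in the same 6 libraries, so this interval does not measure the spread between libraries. The medians were 0.05 (70 called higher, 59 lower) and -0.09 (36 higher, 110 lower), so much of the difference lies in the matched genes, and more unspliced RNA fits it but is not shown by it. Whether genotype or library preparation set it cannot be told apart, because the labels give no batch. An exact two-sided permutation test of the share (p = 0.133, smallest possible 0.0667) cannot decide between them, and Cmtr1 cKO 4 (38.02%) lies close to control 1 (37.23%).

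Gm33707, a processed pseudogene of Eno1 (chromosome 3, 60769887 to 60770455, minus strand, GRCm38; chosen after its values were seen), had 0 counts in both controls and 299, 302, 263 and 227 in Cmtr1 cKO 1 to 4, at least 87.9-fold higher against a floor of 3 counts per library. Eno1 (enolase) had a log2 fold change of -0.08. Its reads, if misplaced at the same rate in both genotypes, would have put 285 or more reads on Gm33707 in each control. A rate of misplacement that differs with genotype was not tested. A stretch of chromosome that differs between the genotypes, such as one carried with the Cre transgene, may be the source. That cannot be told apart from other links to the genotype, since 6 genes were tested within 1 Mb, 2 of them called (Rap2b at -0.35 and Gm37488 at 0.76; exact one-sided hypergeometric test of the number called, p = 0.143), and all libraries with the transgene carry the label Cmtr1 cKO.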

How the results depend on the processing

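The covariate and all values under it were added after seeing the data. Since the share separates the genotypes, values under it cannot tell an effect of library preparation from an effect of genotype. Counts of changed genes with the other size factors, DESeq2, the stricter filter, unstranded counts, protein-coding genes alone and the length and GC correction stayed within 1.5 times 1457 (1269 to 1701). Quality weights gave 3139 (1473 higher, 1666 lower), no filter 2272 (1167 higher, 1105 lower), a minimum log2 change of 1 gave 265 (133 and 132) and the covariate 666 (320 and 346). The replicate block gave 4842 (2394 and 2448). Its numbers are not said to pair the libraries, and numbers 3 and 4 exist in Cmtr1 cKO alone. The block takes up Cmtr1 cKO 3 and 4, so its fold changes compare only Cmtr1 cKO 1 and 2 with the controls. The deviations of libraries 1 and 1 and of 2 and 2 correlated at 0.13 and -0.13. With 2 controls the deviations of the controls mirror each other, and Cmtr1 cKO 1 and 2 were alike, so these opposite signs do not test a pairing. Leaving out 1 library gave 193 to 3880 changed genes, 39 to 1940 higher and 154 to 1940 lower. A lone control is then assumed to vary like the Cmtr1 cKO libraries. Fewer samples lower the counts, while the rise without Cmtr1 cKO 4 fits its place between the groups on the first component. Of 1457 calls 0 changed sign, except 5 on unstranded counts.

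The 19 lists past the threshold became 0 with an estimated correlation (smallest adjusted p = 0.124) and 13 with fry, 11 of them in common, and 15 to 22 under the other alternatives. Fry did not call histones (adjusted p = 0.397), interferon-stimulated genes (0.281), nuclear oxidative phosphorylation (0.281) or innate RNA sensing (0.199). Nor did it call B cell markers (0.123), migration (0.0728), structured RNAs (0.0558) or class I presentation (0.0525). Histones also lost their call with DESeq2 (adjusted p = 0.0668), quality weights (0.0783) and unstranded counts (0.0736), innate RNA sensing with quality weights (0.0758) and unstranded counts (0.0994), structured RNAs on unstranded counts (0.0675), and thymocyte markers with quality weights (0.0833), unstranded counts (0.122) and the length and GC correction (0.0777). With the replicate block histones (median 0.079, adjusted p = 0.75), innate RNA sensing (0.0624) and thymocyte markers (0.0647) lost their calls and naive genes gained one (0.0486). TCR signalling gained one without a filter (0.00746) and on protein-coding genes (0.018), and myeloid markers without a filter (0.004). Cmtr1 was called higher with the replicate block (0.66, adjusted p = 0.000246) and without Cmtr1 cKO 4. Both settings keep Cmtr1 cKO 4, the library with the lowest Cmtr1 level (7.57 CPM), out of the fold change. Cmtr1 had 0.17 to 0.58 with a library left out and -0.65 with the covariate, and the cause of the other shifts was not tested. Of 100 named genes that were called, 28 and 24 stayed called without control 1 and 2, 61 to 97 without a Cmtr1 cKO library and 50 with the covariate. The 121 named genes gave 2032 values under alternatives, of which 1658 kept sign and side of the threshold, 338 lost the call, 22 gained one and 14 changed sign. The 33 lists gave 624, of which 525, 57, 14 and 28 did so.

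With the covariate the log2 values of Ddx3y (-0.096), Itga2b (-0.17), Blk (0.22), Eno1 (0.14), Mat2a (-0.013) and Rngtt (-0.082) changed sign. Lists that changed direction in camera there, with their medians, were oxidative phosphorylation (0.087), mitochondrial ribosome (0.15), regulatory T (0.14), cytokine receptors (0.0097) and naive genes (-0.013). With a library left out Hbb-bs ran from -1.67 to 0.22, Blk from -0.99 to 0.43, Ikzf2 from -0.13 to 0.44, Eng from -0.055 to 0.56 and CT010467.1 from -0.92 to 6.43. CT010467.1 had -1.303 with the replicate block, and Mir6236 had 4.69 on unstranded counts.

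Lists with medians near 0 also changed direction in camera or fry, which need not follow the sign of the median. Cap enzymes turned to lower in that sense, with positive medians of 0.049 with quality weights, 0.048 on unstranded counts, 0.014 with the replicate block, 0.061 in fry, and ranged over 0.013 to 0.074 with a library left out. With the block 1 of the 23 was called higher and 4 lower. Proteasome genes had -0.038 with quality weights, -0.014 on unstranded counts, -0.087 with the block and -0.051 to 0.051 with a library left out. The mitochondrial ribosome had -0.046 in DESeq2, -0.020 on protein-coding genes, 0.0011 after length and GC correction and -0.080 to 0.0028 with a library left out. Ribosome biogenesis had -0.017 with the block and 0.0091 to 0.066 with a library left out, and immediate early genes had 0.042 with the block. Regulatory T genes ran from -0.22 to 0.11 and histones from 0.0019 to 0.47 with a library left out. The cause was not tested for these.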

Other observations

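The grouping of the genes in this part was chosen after the data were seen, and so were its tests.

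All 57 joining segments of the T cell receptor alpha locus tested had a positive log2 fold change, with a median of 0.89 and 4 called higher (26 adjusted over the list alone), among them Traj53 (1.55) and Traj50 (1.37). Sense-intronic genes had a median of 0.65 with 14 of 107 higher and 1 lower (24 and 1 adjusted over the list alone). TEC genes had a median of 0.58 with 56 of 569 higher and 5 lower (53 and 5 adjusted over the list alone). Where TEC genes lie relative to introns was not analysed here. When control 1, control 2 or Cmtr1 cKO 1, 2 or 3 was left out, 0 joining segments, 0 or 1 sense-intronic genes and 0 to 22 TEC genes were called higher, and without Cmtr1 cKO 4 these numbers were 53, 55 and 283. Medians stayed positive in all of these (0.72 to 1.096, 0.55 to 0.78 and 0.48 to 0.71), and with the share of reads outside exons as a covariate the medians were -0.15, -0.02 and -0.05. The joining segments lay at 1.23, 1.24, 0.75 and 0.06 against the control mean in Cmtr1 cKO 1 to 4.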
